A study of Streptomyces xinghaiensis with 12 samples.

How the data were processed

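Messenger RNA was profiled by RNA-seq in 12 libraries from 4 strains of Streptomyces xinghaiensis, a filamentous soil bacterium that makes the macrolide antibiotic tylosin. Per the labels, total RNA came from cells harvested at 96 h of fermentation, with 3 libraries per strain. TLPH152 carries the empty integrating vector and served as the control. TLPH08-2 overexpresses tlrC, TLPH11 overexpresses metK, adoK and metF, and TLPH17 is labelled as overexpressing the same genes and tylR. The labels number the samples of a strain as replicates but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

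The authors deposited 4 tables, one per strain, each with the same 6152 annotated genes, their coordinates and 6 value columns. Read counts per gene are in the deposited columns named count, with no normalization per the file headers. The columns named FPKM hold whole numbers and were treated as a rounded score: in TLPH152 and TLPH08-2 each deposited value lay within 0.51 of the count divided by gene length and library total, so the authors' FPKM carry only a scaling to the library total. CASAVA 1.8, Bowtie2 and bedtools 2.16.1 are named in the submitters' processing notes, without their roles. The genome build, the annotation version and the strand setting of the counting are not given in the sources used here. Gene lengths were multiples of 3 in 100.0% of genes, so they are coding lengths, and the tables list no ribosomal or transfer RNA gene. Reads of overlapping or antisense genes, and reads shared between near-identical copies, therefore cannot be separated, and values for such genes are uncertain. Gene descriptions in the tables mostly name proteins of Streptomyces fradiae; gene identifiers and coordinates are those of the tables.

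Columns were assigned to strains by the strain name in their header. The column numbers of TLPH11 and TLPH17 differ from the replicate numbers in the labels, so those columns were used as libraries of the strain without a number of their own and are named 1 to 3 in column order. TLPH152 and TLPH08-2 columns carry the numbers of the labels. The FPKM columns of TLPH11 and TLPH17, 6 columns that match no single labelled sample, were not used.

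Library totals ran from 3654149 to 5754427 counts. The limit that a count of 0 allows, 3 counts, corresponds to between 0.521 and 0.821 CPM, the counts scaled to a common library total, and covers counting error only. Libraries of the same strain were compared by a chi-square of their counts over genes with enough counts. The statistic per degree of freedom lay between 5.37 and 16.5, so no pair differed by as little as sampling noise and all 12 libraries were counted separately.

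Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 5143 genes holding 99.93% of the counts and set aside 1009. Libraries were scaled by trimmed mean of M values (TMM), and a quasi-likelihood model with one mean per strain was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.148. Each contrast was tested with the quasi-likelihood F test and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A gene is said to have risen, fallen or changed only when it passed that threshold. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Mean CPM are TMM-scaled and given with their SD over 3 libraries. TMM factors were 0.855, 0.862 and 0.806 in the TLPH152 libraries and 0.979 to 1.14 in the other strains.

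The comparisons, the tests, 28 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Planned comparisons were each of the 3 strains against TLPH152 and TLPH17 against TLPH11. Direct comparisons of TLPH08-2 with TLPH11 and with TLPH17 were added after the data were seen. Named genes are the genes the labels give as overexpressed, the 8 largest rises and 8 largest falls per comparison, and up to 4 members with the smallest p of each list described. A rise or fall qualified when the 3 and 3 libraries did not overlap, the mean reached 20 CPM in 1 of the strains, and the gene had an informative description. Genes named outside that rule were chosen after their values were seen, and the text says so. Of the overexpressed genes, tlrC, metK, metF and tylR were found by their descriptions and adoK by its KEGG orthologue, adenosine kinase. List members were found by the description text, or by the orthologue description where the gene description was uninformative. The list meant for ribosomal and transfer RNA as a sign of library quality matched only 11 protein genes, mostly RNA-modifying enzymes, and says nothing about RNA quality.

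Gene lists with 3 or more tested members were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other genes. List p-values were adjusted over the lists of a comparison. The whole tylosin locus and versions of the lists without the overexpressed genes were added after the data were seen. Overlaps between comparisons that share the control libraries were set beside the product expected of independent calls and beside 20 simulations of unchanged strains against shared controls.

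The calling and list tests were first tested on simulated counts for TLPH08-2 versus TLPH152 over 5143 genes. Of the genes changed by a log2 of 0.5, 1 and 2, 13.6%, 65.7% and 85.1% were recovered. There were 113 calls, of which 3 were false, or 2.7%. A planted list of changed genes had a camera adjusted p of 2.3e-54, and 0 of 20 unchanged lists were called. Genes were simulated independently, so the members of these lists were not correlated. The list result therefore does not give the error rate of the list test on real lists.

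Each result was recomputed with DESeq2 1.42.0 size factors in the same model, the DESeq2 Wald test, no filter on low counts, leaving out the 10 highest-count genes, a fit of only the 6 libraries compared, a replicate block (TLPH08-2 and TLPH152 only, fitted to 6 libraries once the column numbers were seen), a fold-change minimum, and leaving out each library in turn. Scaling by library totals alone, the scale of the deposited FPKM of TLPH152 and TLPH08-2, was added after the data were seen, as were most of these settings for gene lists and shared calls. It moved the median log2 fold change of all genes by 0.33 in TLPH08-2, 0.28 in TLPH11 and 0.39 in TLPH17 against TLPH152, and by 0.12 in TLPH17 against TLPH11. Fold changes are given on the TMM scale, relative to the median gene. An alternative without ribosomal RNA was not run, since no such gene is listed, and a pseudocount alternative did not apply to counts.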

Results

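The series compared gene expression in tylosin-producing strains of Streptomyces xinghaiensis after 96 h of fermentation. Tylosin is a macrolide antibiotic: a polyketide ring is assembled by modular polyketide synthases and then decorated with deoxysugars and O-methyl groups, the latter taken from S-adenosylmethionine. RNA-seq read counts were available for 3 libraries each of the vector control TLPH152, the tlrC strain TLPH08-2, the metK, adoK and metF strain TLPH11, and the strain TLPH17, labelled as carrying tylR in addition. Library totals were 4867570, 4319365 and 4594585 counts in TLPH152, 4608251, 4459832 and 3654149 in TLPH08-2, 4466146, 3969733 and 4037856 in TLPH11, and 5754427, 4775601 and 4233753 in TLPH17. Across genes, which are not independent replicates, log2 CPM of libraries of one strain correlated with r from 0.965 to 0.983. The range was 0.926 to 0.948 between a control library and a library of another strain, and 0.953 to 0.974 between libraries of the 3 other strains. The first principal component held 36.7% of the variance and placed the control libraries between -37.1 and -35.3 and all others between 5.2 and 20.2. TLPH08-2 library 3, the smallest library, lay at -35.1 on the third component, where the other 11 libraries lay between -7.6 and 10.8. It had 545 genes with a count of 0, against 303 and 301 in the other libraries of that strain.

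The genes that the labels name as overexpressed lie side by side at the end of the tylosin locus, on the sequence the tables call chr. The transcript of tlrC (gene54, 96237 to 97883, minus strand), whose product is an ABC-F protein that protects the ribosome from tylosin, rose 3.81-fold in TLPH08-2. It went from 438.4 ± 61.3 to 1670.6 ± 130.9 CPM (SD, n = 3 each; log2 fold change 1.93 ± 0.12 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.2e-10). In TLPH11 metK (gene51, 92580 to 93941, plus strand), encoding S-adenosylmethionine synthase, rose 10.7-fold from 950.7 ± 133.7 to 10192.7 ± 475.8 CPM (log2 3.42 ± 0.10 SE, adjusted p = 1.8e-15). The adenosine kinase gene adoK (gene52, 93973 to 95073) rose 5.92-fold from 292.3 ± 44.9 to 1729.5 ± 54.7 CPM. The gene metF (gene53, 95070 to 95987), encoding the methylenetetrahydrofolate reductase that supplies methyl groups for methionine, rose 2.91-fold from 326.5 ± 33.3 to 949.4 ± 53.6 CPM. In the libraries labelled TLPH17 metK rose 7.99-fold to 7594.7 ± 476.5 CPM, while adoK and metF rose 2.04-fold and 1.67-fold, to 595.8 ± 33.7 and 545.4 ± 46.4 CPM. These genes also rose in TLPH08-2, by log2 0.83 ± 0.09 for metK, 0.80 ± 0.11 for adoK and 0.56 ± 0.10 for metF. Mean adoK and metF there were 510 and 481.8 CPM, near those of the libraries labelled TLPH17, though the label of TLPH08-2 names neither gene. The rises of adoK and metF in the libraries labelled TLPH17 therefore cannot be assigned to added copies from these counts. Mean metK in TLPH08-2 was 1690.6 CPM, far below its level in those libraries.

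The label of TLPH17 names tylR as a further overexpressed gene, and the counts did not show a rise of it. Counts of tylR (gene50, 90444 to 91736, minus strand), encoding a pathway regulator of tylosin synthesis, were 3117.3 ± 98.0 CPM in TLPH152, 2761.9 ± 205.8 in TLPH08-2, 2359.9 ± 79.4 in TLPH11 and 2510.5 ± 90.3 in the libraries labelled TLPH17. Against TLPH152 tylR fell in the libraries labelled TLPH17 (log2 -0.31 ± 0.08 SE, edgeR adjusted p = 0.0056) and in TLPH11 (-0.40 ± 0.08, 0.001). It did not pass in TLPH08-2 (-0.17 ± 0.08, 0.13). The difference between the libraries labelled TLPH17 and TLPH11 was 0.09 ± 0.08 with an adjusted p of 0.52. With scaling by library totals alone the value for the libraries labelled TLPH17 against TLPH152 turned to 0.08 (adjusted p = 0.39) and that for TLPH08-2 to 0.15 (adjusted p = 0.13), and that for TLPH11 was -0.12 (adjusted p = 0.23), so neither fall passed. Because of this, the strain is named below by its label only, and no direction is read as an effect of tylR.

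**Figure D1:**
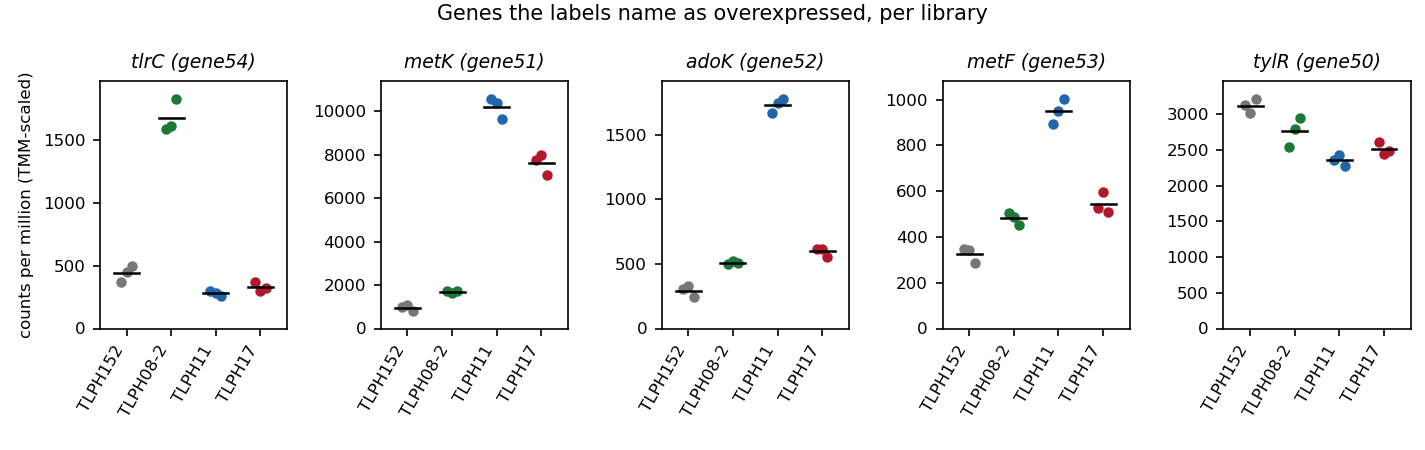
TMM-scaled CPM of the genes named as overexpressed, on a linear axis from 0, for each of the 12 libraries (points) with the mean of 3 libraries per strain (line). Means of tlrC were 438.4 in TLPH152 and 1670.6 in TLPH08-2, those of metK 950.7 in TLPH152 and 10192.7 in TLPH11, and those of tylR 3117.3 in TLPH152 and 2510.5 in the libraries labelled TLPH17.

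Comparing TLPH08-2 with TLPH152 shows what differed in the strain with raised tlrC. Tylosin genes rose together: of the 20 tested members of the tylosin cluster list 15 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.58. Besides tlrC, the largest calls were gene29, encoding the mycarose methyltransferase TylCIII (log2 1.45 ± 0.11, edgeR adjusted p = 2.7e-09), gene32, a dTDP-4-dehydrorhamnose 3,5-epimerase (1.13 ± 0.12). Another was gene16, encoding macrocin O-methyltransferase, which catalyses the last step to tylosin (1.09 ± 0.10, from 1365.7 ± 192.5 to 2914.0 ± 197.5 CPM, n = 3 each). Of 11 tested genes for deoxysugar synthesis and transfer 9 rose and 2 fell (9 and 2 adjusted over the list alone), among them gene46, encoding glucose-1-phosphate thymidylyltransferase (0.77 ± 0.09), and gene28, encoding the ketoreductase TylCIV (0.73 ± 0.09). Both genes lie within the tylosin locus, so the deoxysugar list and the cluster list are not separate results. The cluster list passed camera at an adjusted p of 1.4e-09, or adjusted p = 0.005 with an estimated correlation. The deoxysugar list passed at 5.8e-06, or adjusted p = 0.09 with an estimated correlation.

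Of the 5 polyketide synthase genes, gene38 to gene42, 1 rose in TLPH08-2 and 4 did not pass. They were looked at after their values were seen. Their log2 fold changes in TLPH08-2 were 0.19, 0.15, -0.10, -0.17 and 0.24, and only gene42, encoding the starter module and modules 1 and 2 of tylactone synthase, passed (0.24 ± 0.06, adjusted p = 0.0074). Counts of the locus, 45 contiguous genes from gene10 to gene54 (11686 to 97883), made up 13.3% ± 0.45 of all counts in TLPH152 (SD, n = 3), 19.6% ± 0.71 in TLPH08-2, 17.6% ± 0.38 in TLPH11 and 19.1% ± 0.68 in the libraries labelled TLPH17. On that scale of library totals gene42 held 3.67% ± 0.10 in TLPH152 and 5.45% ± 0.18, 4.48% ± 0.097 and 4.85% ± 0.27 in the other strains in the same order. The synthase gene gene40 held 2.42% ± 0.09 in TLPH152 and 2.84% ± 0.11, 2.52% ± 0.039 and 2.42% ± 0.11, and gene41 held 1.88% ± 0.069 and 2.10% ± 0.078, 2.06% ± 0.024 and 1.89% ± 0.095. The type I polyketide synthase list, with 3 tested members, had a median of -0.17 in TLPH08-2 that turned to 0.16 with library totals.

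**Figure D2:**
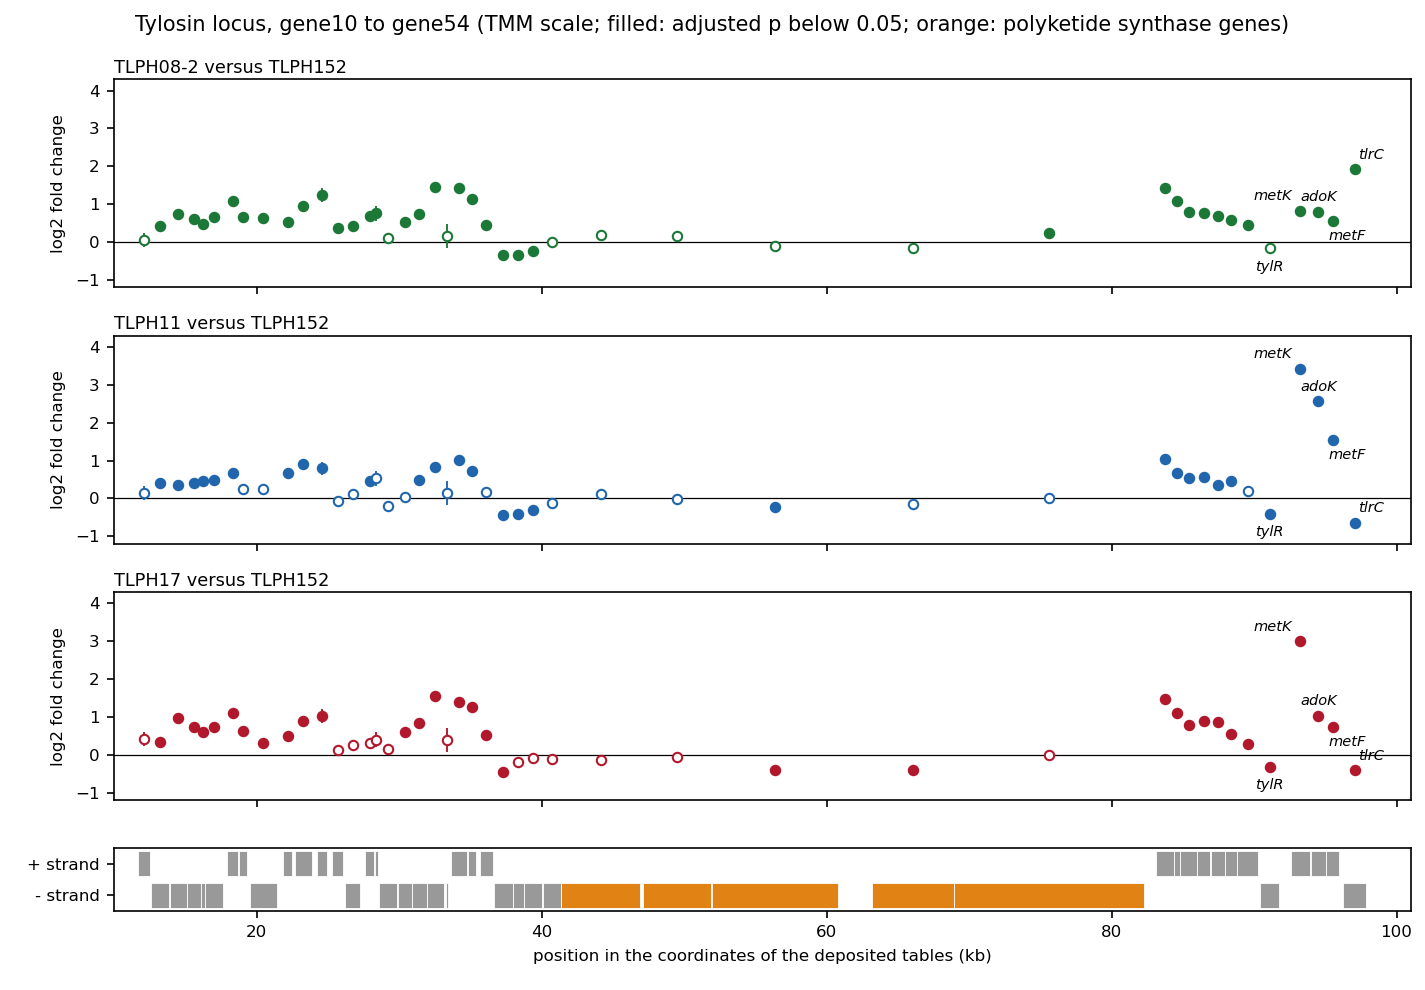
Log2 fold change on the TMM scale (vertical axis; bars are SE) of the 45 genes of the tylosin locus against TLPH152, by position in kb; filled points have an adjusted p below 0.05, and the lowest panel gives gene extents by strand with polyketide synthase genes in orange. Of the 45 genes 33 rose in TLPH08-2, 23 in TLPH11 and 27 in the libraries labelled TLPH17, and 3, 6 and 5 fell; with library totals the fold changes of the synthase genes move up by the shift of the median gene.

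Among the genes of other secondary metabolites in TLPH08-2, 11 of 24 tested fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.0014, or adjusted p = 0.29 with an estimated correlation). The precursor peptide of a thiazolylpeptide bacteriocin (gene1161, 1437408 to 1437584) fell 69.3-fold from 661.6 ± 52.1 to 9.40 ± 2.08 CPM (log2 -6.12 ± 0.34). The non-ribosomal peptide synthetase genes gene534 and gene535 fell by 2.24 ± 0.19 and 3.28 ± 0.30 on the log2 scale. The list had a median of -0.34 and a mean of -1.24, so large falls of part of its members weighed on the mean. It does not hold every such gene: in the siderophore run gene1276 to gene1285 8 of 10 genes rose in TLPH08-2, and these were not members. The count of 0 rises in this list, here and in the other strains, covers its members only. Genes of the tricarboxylic acid cycle rose in 14 of 23 tested members and fell in 2 (14 and 2 adjusted over the list alone), including subunits of succinate-CoA ligase (gene2479, 0.82 ± 0.12) and succinate dehydrogenase (gene2440, 0.93 ± 0.13). In the respiratory chain and ATP synthase list 24 of 57 rose and 6 fell (24 and 8 adjusted over the list alone), led by the terminal oxidase genes gene4976 (1.18 ± 0.12) and gene4975 (1.04 ± 0.11). Sporulation genes fell in 16 of 36 tested and rose in 4 (17 and 4 adjusted over the list alone). The SsgA-family cell division regulator gene3148 fell by 1.96 ± 0.14 and the stage II sporulation protein E gene gene447 by 1.78 ± 0.23, while the CotH gene gene421 rose 4.61-fold (2.20 ± 0.20). Sigma and anti-sigma factor genes fell in 14 of 46 tested and rose in 3 (14 and 4 adjusted over the list alone), including the SigE-family gene gene2393 (-3.40 ± 0.17) and sigB (gene3835, -1.07 ± 0.11), with a list median of -0.24 that turned to 0.09 with library totals. Camera adjusted p were 0.0034, 0.002, 0.0059 and 0.015 for the last 4 lists in the order given. Their adjusted p with an estimated correlation were 0.29, 0.31, 0.23 and 0.27.

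Large rises of single genes in TLPH08-2 included gene2927, encoding a sugar-binding transport protein (7.86-fold, 7.94 ± 1.19 to 62.7 ± 22.9 CPM), the esterase gene gene4934 (4.51-fold), the MFS transporter gene gene2403 (4.27-fold) and the IucA/IucC family gene gene1278 (4.13-fold). The largest fall was in gene5957, encoding a tricarboxylate-binding transport protein, from 102.1 ± 53.0 to 1.16 ± 0.356 CPM (log2 -6.39 ± 0.44). The GntR-family regulator gene gene3086 fell 13.5-fold (-3.76 ± 0.18, from 132.7 ± 5.08 to 9.65 ± 2.64 CPM). Members of the S-adenosylmethionine list rose in 6 of 17 tested and fell in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.057), with methionine synthase (gene5462, 1.16 ± 0.10) and adenosylhomocysteinase (gene4023, 0.95 ± 0.10) among those that rose. In the acyl-CoA precursor list, which supplies the extender units of the ring, 4 of 14 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.3), with methylmalonyl-CoA mutase (gene2429) at 0.98 ± 0.18. In all, 1484 of 5143 genes changed (28.9%), 682 up and 802 down, or 46% up. Scaling by library totals gave 2084 with 1613 up, or 77.4%. Libraries of the strains did not overlap for 1997 genes, where chance gives 10%.

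TLPH11 against TLPH152 addressed the added methionine-cycle genes. Apart from metK, adoK and metF, the S-adenosylmethionine list showed no common direction: of the 14 tested members left, 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.88). The full list, with 6 of 17 up and 3 down (7 and 3 adjusted over the list alone), passed camera at an adjusted p of 0.016, or adjusted p = 0.36 with an estimated correlation. Without the overexpressed genes the median was 0.21, the mean -0.13 and the fry direction down. A second set of the same enzymes fell, with gene5714, annotated as methionine adenosyltransferase, down 5.59-fold from 84.8 ± 10.5 to 15.1 ± 2.93 CPM (log2 -2.48 ± 0.17, edgeR adjusted p = 9.7e-10, n = 3 each). Tylosin cluster genes rose in 10 of 20 tested and fell in 4 (11 and 4 adjusted over the list alone), including gene29 (0.83 ± 0.11), gene16 (0.66 ± 0.10) and gene19, encoding the gamma-butyrolactone receptor TylP (0.68 ± 0.09). The resistance gene tlrC fell by 0.64 ± 0.12. Deoxysugar genes rose in 6 of 11 and fell in 2 (8 and 2 adjusted over the list alone), among them gene46 (0.57 ± 0.09).

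Ribosomal protein genes fell in 23 of 55 tested and rose in 5 in TLPH11 (23 and 6 adjusted over the list alone), with a list median of -0.25 that turned to 0.03 with library totals. L10 (gene2656, -0.84 ± 0.10) and L7/L12 (gene2655, -0.91 ± 0.13) fell, and S1 (gene5146, 0.52 ± 0.10, from 4452.1 ± 284.3 to 6398.4 ± 185.2 CPM) rose. Phosphate starvation genes fell in 6 of 14 tested and rose in 0 (7 and 0 adjusted over the list alone), including the phosphate-binding protein gene pstS (gene3504, -0.93 ± 0.11) and an alkaline phosphatase gene (gene4853, -2.11 ± 0.30). The respiratory list rose in 16 of 57 and fell in 4 (17 and 4 adjusted over the list alone), with cytochrome c oxidase subunit II (gene4975) at 0.67 ± 0.11, whereas the non-electrogenic NADH dehydrogenase gene gene3955 fell by 0.91 ± 0.10. Genes of other secondary metabolites fell in 8 of 24 and rose in 0 (9 and 0 adjusted over the list alone), with gene1161 down 225-fold from 661.6 ± 52.1 to 2.92 ± 0.71 CPM. Camera adjusted p were 0.01 for ribosomal proteins and 0.016 for the tylosin, deoxysugar, phosphate, respiratory and other secondary metabolite lists. In the same order, the adjusted p with an estimated correlation were 0.43, 0.36, 0.41, 0.36, 0.55 and 0.5. The respiratory call was lost without TLPH11 library 3 (adjusted p = 0.069), and with library totals the S-adenosylmethionine, ribosomal and phosphate lists had adjusted p of 0.067, 0.16 and 0.053.

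Other large changes in TLPH11 were rises of the MFS transporter gene gene2403 (7.11-fold, 7.36 ± 2.63 to 52.8 ± 2.51 CPM), the esterase genes gene4934 and gene4936 (5.86-fold and 4.72-fold) and gene1545, encoding a cellulose-binding protein (3.91-fold). The transporter gene gene5957 fell 84.2-fold and the regulator gene gene5410 fell 19.1-fold (-4.25 ± 0.26). In the acyl-CoA list 2 of 14 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.88), with methylmalonyl-CoA carboxyltransferase (gene1799) down by 0.87 ± 0.10. The calls of the other members, gene1899, gene2508 and gene1215, at adjusted p of 0.033, 0.04 and 0.04, were each lost on leaving out a library. In total 1276 genes changed (24.8%), 580 up and 696 down, or 45.5% up. Library totals gave 1744 with 1352 up, or 77.5%. Libraries did not overlap for 2037 genes.

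Against TLPH152, the libraries labelled TLPH17 had raised tylosin genes: 12 of 20 tested rose and 3 fell (13 and 4 adjusted over the list alone), with a median of 0.54. Examples are gene29 (log2 1.54 ± 0.11, from 654.9 ± 44.8 to 1901.7 ± 123.9 CPM, n = 3 each, edgeR adjusted p = 8.2e-10), gene12, encoding demethylmacrocin O-methyltransferase (0.97 ± 0.09), and gene16 (1.09 ± 0.10). In the deoxysugar list 9 of 11 rose and 1 fell (9 and 2 adjusted over the list alone), including dTDP-glucose 4,6-dehydratase (gene47, 0.86 ± 0.09). Polyketide synthase genes gene40 and gene41 fell on the TMM scale by 0.40 ± 0.07 and 0.39 ± 0.07 (both named after their values were seen), while the list median of -0.39 moved to 0 with library totals. The resistance gene tlrC fell by 0.41 ± 0.12 (adjusted p = 0.0084), a call that was lost without TLPH17 library 2 (-0.34, adjusted p = 0.054) and with library totals (-0.01, adjusted p = 0.93).

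In the libraries labelled TLPH17, of 57 tested respiratory genes 27 rose and 6 fell (30 and 6 adjusted over the list alone), with cytochrome c oxidase subunit II (gene4975) up 3.14-fold from 187.6 ± 17.3 to 589.1 ± 8.71 CPM and ATP synthase subunit A (gene1937) up 2.73-fold. Tricarboxylic acid cycle genes rose in 13 of 23 and fell in 3 (14 and 3 adjusted over the list alone), with succinate dehydrogenase genes gene2438 (1.61 ± 0.16) and gene2440 (1.09 ± 0.13) and the succinate-CoA ligase gene gene2479 (1.26 ± 0.12). In the S-adenosylmethionine list 8 of 17 rose and 3 fell (8 and 4 adjusted over the list alone), among them adenosylhomocysteinase (gene4023), which removes the product of methyl transfer (1.65 ± 0.10), while gene5714 and gene5716 fell by 2.23 ± 0.17 and 2.36 ± 0.21. Genes of other secondary metabolites fell in 11 of 24 and rose in 0 (11 and 0 adjusted over the list alone). Acyl-CoA precursor genes rose in 7 of 14 and fell in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.24), including methylmalonyl-CoA epimerase (gene1913, 0.92 ± 0.18). Camera adjusted p were 4.5e-05 for the tylosin, 2.7e-05 for the deoxysugar, 2.7e-05 for the respiratory, 0.0047 for the tricarboxylic acid, 0.03 for the S-adenosylmethionine and 0.00015 for the other secondary metabolite list. In the same order, the adjusted p with an estimated correlation were 0.054, 0.12, 0.28, 0.34, 0.29 and 0.28. The S-adenosylmethionine call was lost without TLPH17 library 2 (adjusted p = 0.059), with library totals (0.13) and without the overexpressed genes (0.44; median 0.24, mean -0.01).

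Large rises in the libraries labelled TLPH17 included the MFS transporter gene gene2403 (18.2-fold, 7.36 ± 2.63 to 135.2 ± 21.5 CPM, log2 4.19 ± 0.24), the endonuclease V gene gene1019 (10.8-fold) and the xylanase gene gene1054 (5.29-fold). The IucA/IucC family gene gene1278 rose 4.87-fold. Large falls included gene5957 (52.5-fold), the transporter gene gene5955 (35.6-fold) and gene4814, a serine/threonine protein kinase gene next to a lantipeptide gene (27.5-fold, 297.2 ± 120.1 to 10.8 ± 2.01 CPM), and gene1161 fell 17-fold to 38.9 ± 27.7 CPM. In total 1762 genes changed (34.3%), 783 up and 979 down, or 44.4% up. Library totals gave 2458 with 1925 up, or 78.3%. Libraries did not overlap for 2398 genes.

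TLPH17 and TLPH11 differ by tylR in their labels, and the direct comparison showed lower counts of metK, adoK and metF and higher counts of groEL and groES genes in the libraries labelled TLPH17. Transcripts of adoK fell from 1729.5 ± 54.7 to 595.8 ± 33.7 CPM (log2 -1.54 ± 0.11, edgeR adjusted p = 2e-09, n = 3 each), those of metF 1.74-fold and those of metK 1.34-fold. The chaperonin genes, whose products fold other proteins, rose: groEL (gene3652) 6.26-fold from 799.3 ± 70.1 to 5001.4 ± 230.2 CPM (2.65 ± 0.11), a second groEL (gene2564) 5.43-fold and groES (gene2565) 6.17-fold. In TLPH152 the means of gene3652, gene2564 and gene2565 were 1681.5, 646 and 333.6 CPM. For all 3 genes TLPH11 thus lay below the control and the libraries labelled TLPH17 above it, so part of each fold comes from the lower level in TLPH11. In the chaperone and protease list as a whole 8 of 28 tested rose and 4 fell (8 and 5 adjusted over the list alone), with a median of -0.03 and a mean of 0.12. The list did not pass camera in any comparison. Thiazolylpeptide gene gene1161 and regulator gene gene3086 rose 13.2-fold and 10.7-fold, and gene3086 was at 99.8 ± 4.35 CPM against 9.31 ± 1.75. Their means in TLPH152 were 661.6 and 132.7 CPM, so for both genes TLPH11 lay further below the control than the libraries labelled TLPH17. The kinase gene gene4814 fell 25.4-fold (-4.67 ± 0.27), the catalase gene gene211 fell 5.42-fold and the oxidoreductase gene gene5931 fell 5.57-fold.

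Tylosin cluster genes rose in 8 of 20 tested in the libraries labelled TLPH17 against TLPH11 and fell in 0 (11 and 1 adjusted over the list alone), including gene12 (0.61 ± 0.09), gene29 (0.71 ± 0.11) and gene27, encoding the enoyl reductase TylCII (0.55 ± 0.09). Deoxysugar genes rose in 8 of 11 and fell in 1 (9 and 1 adjusted over the list alone). Phosphate starvation genes rose in 8 of 14 and fell in 0 (9 and 1 adjusted over the list alone), with the transporter genes gene3504 (0.72 ± 0.11) and gene3503 (1.05 ± 0.17). Against TLPH152 that list fell in TLPH11 and had a median of 0.06 in the libraries labelled TLPH17 (camera adjusted p = 0.66). Mean CPM in TLPH152, TLPH11 and the libraries labelled TLPH17 were 530.8, 278.1 and 458.8 for gene3504, and 62.5, 47.7 and 98.7 for gene3503. Pentose phosphate genes fell in 7 of 20 and rose in 0 (7 and 0 adjusted over the list alone), with the transketolase genes gene680 and gene1395 down 2.82-fold and 2.07-fold. Respiratory genes rose in 22 of 57 and fell in 4 (27 and 8 adjusted over the list alone), including ATP synthase subunit C (gene1936, 1.11 ± 0.15). Tricarboxylic acid cycle genes rose in 11 of 23 and fell in 4 (12 and 4 adjusted over the list alone); one of those that fell, gene5239 (-1.29 ± 0.19), encodes a diaminobutyrate transaminase, an enzyme of ectoine synthesis outside the cycle. S-adenosylmethionine genes rose in 3 of 17 and fell in 3 (3 and 3 adjusted over the list alone, camera adjusted p = 0.87). Those that fell were metK, adoK and metF, and the median without the overexpressed genes was 0.13. Acyl-CoA precursor genes rose in 5 of 14 and fell in 2 (6 and 3 adjusted over the list alone, camera adjusted p = 0.09). Camera adjusted p were 0.00036 for the tylosin, 8.8e-05 for the deoxysugar, 0.00036 for the phosphate, 0.013 for the pentose phosphate, 0.00036 for the respiratory and 0.017 for the tricarboxylic acid list. In the same order, the adjusted p with an estimated correlation were 0.079, 0.09, 0.079, 0.096, 0.34 and 0.35. The tricarboxylic acid call was lost without TLPH17 library 2 (adjusted p = 0.064). In total 962 genes changed (18.7%), 433 up and 529 down, or 45% up. Without TLPH11 library 1 it was 642, with 268 up, or 41.7%. Library totals gave 1120 with 720 up, or 64.3%. Libraries did not overlap for 1865 genes.

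**Figure D3:**
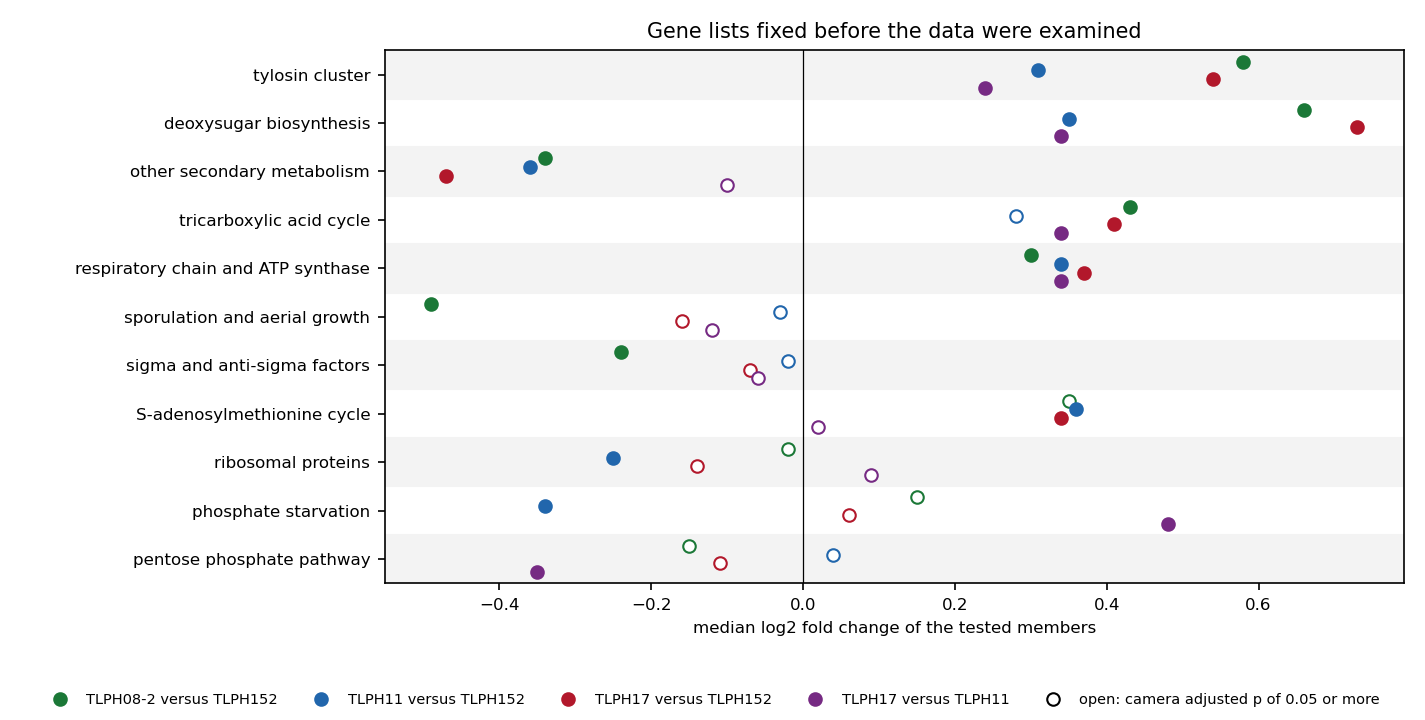
Median log2 fold change on the TMM scale (horizontal axis) of the tested members of the 11 gene lists that passed camera in at least 1 comparison (filled points; open points did not pass), by comparison in color. The tylosin list medians were 0.58, 0.31, 0.54 and 0.24; with library totals the medians of ribosomal proteins in TLPH11 and of sigma factors in TLPH08-2 turn positive, at 0.03 and 0.09.

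Of 26 list calls over the 4 comparisons, 1 held with an estimated correlation, the tylosin cluster in TLPH08-2. The tylosin and deoxysugar lists both hold genes of the tylosin locus, so their calls are not separate results. In versions added after the data were seen, the tylosin cluster without the overexpressed genes had an adjusted p = 0.0088 with an estimated correlation in TLPH08-2 and 0.029 in the libraries labelled TLPH17. The whole locus had 0.01 and 0.045, and 0.026 and 0.082 without the overexpressed genes. On the TMM scale with all libraries, another 17 lists passed in none of these 4 comparisons, with camera adjusted p of 0.09 or more: acyl-CoA precursor supply, RNA-modifying enzymes, MFS transporters, nitrogen assimilation, chaperones and proteases, type I polyketide synthases, fatty acid beta-oxidation, branched-chain amino acid catabolism, oxidative stress defence, extracellular hydrolases, mobile elements, iron uptake, ABC transporters, fatty acid synthesis, translation factors, glycolysis, and gamma-butyrolactone signalling. With library totals, translation factors passed camera in TLPH08-2 (adjusted p = 0.018) and in the libraries labelled TLPH17 (0.048), and nitrogen assimilation in TLPH08-2 (0.034). Leaving out 1 library let nitrogen assimilation pass in TLPH08-2 (0.043) and acyl-CoA precursor supply in TLPH17 versus TLPH11 (0.048).

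Genes changed against the control overlapped between the strains. TLPH08-2 and TLPH11 shared 861 genes called the same way, 388 up and 473 down, where independent calls would share 76.9 and 108.5, and 7 genes were called in opposite directions. TLPH08-2 and the libraries labelled TLPH17 shared 1127, 483 up and 644 down, against 103.8 and 152.7, with 7 opposite. TLPH11 and the libraries labelled TLPH17 shared 869, 363 up and 506 down, against 88.3 and 132.5, with 15 opposite. In all 3 strains 314 genes were called higher and 413 lower, among them gene421 and gene2403 (higher) and gene1161, gene5957 and gene5955 (lower), and 2775 of the 5143 genes were called in none. The 3 comparisons use the same control libraries. Covariances of fold changes across genes were 0.437, 0.528 and 0.451, against means in 20 simulations of unchanged strains of 0.052, 0.0516 and 0.0521, and correlations were 0.754, 0.822 and 0.721 against 0.515, 0.527 and 0.524. With 3 control libraries no split leaves 2 in each part, so some or all of the excess may come from the shared controls.

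In the direct comparisons added after the data were seen, TLPH08-2 differed from TLPH11 in 631 genes (324 up, 307 down) and from the libraries labelled TLPH17 in 378 (215 up, 163 down). The tylosin cluster list was higher in TLPH08-2 than in TLPH11, with 9 of 20 genes up and 0 down (13 and 0 adjusted over the list alone), a camera adjusted p of 5.3e-09 and an adjusted p = 0.0065 with an estimated correlation. These values include tlrC, which the label of TLPH08-2 names as overexpressed (means 1670.6 CPM in TLPH08-2 and 281.2 in TLPH11). Between TLPH08-2 and the libraries labelled TLPH17 the whole tylosin locus had a median difference of 0.01 and a camera adjusted p of 0.56.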

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

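Settings fixed before the data were examined left most single gene results as they were, but camera with an estimated correlation left few list calls. A call lost in this way does not by itself show correlation between the members of a list. For the tylosin cluster in TLPH11 the estimated correlation was 0.01, equal to the preset, and the camera adjusted p were 0.36 and 0.016. Chosen only after the results were seen were scaling by library totals, and the lists without the overexpressed genes or with the whole locus. So were the lists under DESeq2 size factors or with no filter on low counts, and the lists and shared calls without the 10 highest-count genes, without each library or in 6 libraries. Of 197 single gene results, 187 kept their direction and their side of the threshold under every setting in which they were tested. Of the 197, 189 were tested without the 10 highest-count genes, 196 in 6 libraries and 56 with the replicate block. Many of them were named for large changes or small p in these data, so their stability does not describe genes in general. They leave out the overexpressed genes in comparisons of strains that the labels set apart by them, such as tylR in the libraries labelled TLPH17. Total counts of changed genes stayed within 1.5 times of those reported under all settings but a fold-change minimum, while the rises in TLPH17 versus TLPH11 went from 433 to 268 without TLPH11 library 1. Leaving out each library in turn gave 1237 to 1461 genes for TLPH08-2 versus TLPH152, 972 to 1098 for TLPH11 versus TLPH152, 1479 to 1590 for TLPH17 versus TLPH152 and 642 to 864 for TLPH17 versus TLPH11. With an absolute log2 fold change of at least 1 the counts were 572, 428, 711 and 306, since fewer genes can pass. Gene lists called numbered 7, 7, 6 and 6 with camera at the preset correlation, 1, 0, 0 and 0 with an estimated correlation, and 15, 16, 19 and 14 with fry, which asks another question. With library totals tylR in the libraries labelled TLPH17 against TLPH152 turned to 0.08 (adjusted p = 0.39), and in TLPH08-2 (gene50) to 0.15 (adjusted p = 0.13), by the shift of scale itself, and the fall in TLPH11 no longer passed (-0.12, adjusted p = 0.23). Replicate numbers of TLPH08-2 and TLPH152 do not pair the libraries; a planned block on them, fitted to 6 libraries once the column numbers were seen, gave 1077 genes and 7 lists. No paired analysis was possible for the other comparisons because their columns carry other numbers than the labels. At these depths a gene with 3 counts lies at 0.521 to 0.821 CPM, so falls to near 0 are bounded by depth.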

Other observations

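Neighbouring genes often changed together in the 3 strains; the runs, blocks and genes of these first paragraphs and their tests were chosen after the values were seen. Of runs of at least 5 neighbours called the same way in all 3 strains against TLPH152 there were 17, 12 lower and 5 higher, with 118 genes, against at most 1 run in 1000 shuffles of gene order. Untested genes lying between neighbours were passed over. A shuffle breaks up genes that are transcribed together, and the 3 comparisons share the control libraries, so an excess over shuffles does not speak to a cause. The thiopeptide genes gene1149 to gene1161 (1419598 to 1437584) fell in 13 of 13 in each strain, with median log2 fold changes of -4.16 in TLPH08-2, -5.06 in TLPH11 and -3.83 in the libraries labelled TLPH17. Of the non-ribosomal peptide genes gene528 to gene538, 10 of 11 fell in each strain (medians -2.24, -2.08 and -2.34), including the tryptophan halogenase gene gene530. A set of phage tail genes, gene2480 to gene2500, fell in 17, 18 and 18 of 19 tested, and another, gene4421 to gene4437, rose in 15, 11 and 14 of 15 tested.

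Calls in other blocks varied between the strains. Gas vesicle genes gene5350 to gene5355 fell in 6 of 6 in TLPH08-2 (median -1.39) and in the libraries labelled TLPH17 (-2.04), and had a median of -0.43 in TLPH11. Carotenoid genes gene2911 to gene2915, with the phytoene desaturase gene gene2912, fell in 5 of 5 in TLPH08-2 (median -1.05) and in the libraries labelled TLPH17 (-1.55), and had a median of 0.20 in TLPH11. The siderophore genes gene1276 to gene1285 rose in 8, 4 and 9 of 10 (medians 1.59, 0.69 and 2.13). Those that rose were not members of the list of other secondary metabolites, in which 0 genes rose. A run with iron ABC transporter genes, gene599 to gene605, fell in all 3 strains (medians -3.06, -2.61 and -3.41). Arginine genes gene5527 to gene5532 fell in 5 of 5 tested in the libraries labelled TLPH17 (median -1.40), and had medians of 0.26 in TLPH08-2 and -0.14 in TLPH11. The gene with the most counts, gene4478, encoding an acetaldehyde dehydrogenase, fell in all 3 strains (-0.89 ± 0.08, -0.59 ± 0.08 and -1.12 ± 0.08), as did the formate acetyltransferase gene gene5792 (-0.98 ± 0.10, -0.74 ± 0.10 and -1.21 ± 0.10).

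The missing rise of tylR in the libraries labelled TLPH17 was weighed with tests chosen only after the result was seen. An exchange with the libraries of TLPH152 is not borne out, since these would then carry raised metK, and their metK lay below that of TLPH08-2 (log2 -0.83 ± 0.09). An exchange with TLPH08-2 is not borne out, as its metK lay at a log2 of -2.17 ± 0.10 from that of the libraries labelled TLPH17, nor is one with TLPH11 for a tylR rise of 0.58 or more, as tylR there lay at -0.09 ± 0.08 from the same libraries, nor is a rise of that size hidden by scaling, as library totals gave 0.08 against TLPH152. A gain of the size of the metF gain in these libraries, 218.8 CPM, would raise tylR by only 0.13 from its level in TLPH11. The observed difference was 0.09 ± 0.08, so such a gain stays open. The metF gain was the smallest of those of metK, adoK and metF. Mean metF also rose in TLPH08-2, from 326.5 to 481.8 CPM, so its gain need not measure what an added copy gives. A gain of the size of the metK gain, 6644 CPM, is not borne out, since tylR held only 2510.5 CPM in these libraries. A strain from outside the series, a copy changed in sequence and any biological explanation were not tested.

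The calls shared by the 3 strains were weighed with several tests, of which those of the covariance as a whole, of the highest-count genes and of the first principal component were chosen only after the result was seen. In 20 simulations of unchanged strains there were at most 0, 0 and 1 shared calls against 861, 1127 and 869. These counts decide nothing, since at most 0, 0 and 1 genes were called at all in the first strain of each pair. Simulated covariances were at most 0.0577, 0.057 and 0.0588 against 0.437, 0.528 and 0.451. Spread between libraries of the size seen within strains is thus not the whole source of the covariance. A deviation common to all 3 control libraries was not simulated, so the part of the shared controls cannot be told. Without the 10 highest-count genes there were 856, 1118 and 861 shared calls, but this moved the median fold change by 0.01 or less, so a part of a few genes taking most of the counts stays open. A control grown or sequenced in another batch cannot be told from a common response of the strains: the gap of 40.5 on the first principal component parts all 3 control libraries from the other 9. The 10 splits of each 6 libraries are too few for a share under 0.05: in each comparison only 1 split, the real one, reached the real count of genes (1484, 1276, 1762 and 962) or of lists (7, 7, 6 and 6), and the highest other split gave 0 genes (461, 318, 319 and 301 unadjusted in edgeR, against 1952, 1847, 2177 and 1593) and 5, 2, 2 and 5 lists.

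A second tract with metK, adoK and metF annotations, gene5698 to gene5717 (6876672 to 6894961), had lower counts in all 3 strains, and its tests were chosen only after the result was seen. Of 19 tested genes 19, 18 and 19 fell in TLPH08-2, TLPH11 and the libraries labelled TLPH17, with medians of -2.37, -2.51 and -2.36. Reads shared with the copies in the tylosin locus would raise the copies here in TLPH11, but the highest of their values was -2.38. Complete loss of the tract is not borne out, since the lowest median count of its genes in a library was 21. The folds differed between the 19 tested genes, with p of at most 1.5e-22 by a chi-square test of heterogeneity. A common loss factor as the only source of the falls is thus not borne out. The test cannot tell whether such a factor acted along with other differences between the genes, so a common loss in part stays open. No biological explanation was tested.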
